A study of Homo sapiens with 10 samples.

How the data were processed

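RNA of RBE cells was sequenced in 10 libraries, 2 for each of 5 groups: shRNA controls, SQLE knockdown, FDFT1 knockdown, DMSO controls and 1 µM lycorine hydrochloride for 24 h. Groups were read from the sample titles. The submitters' processing notes name FastQC, STAR, RSEM and DESeq2, without versions or order, and the builds GRCh38 and GRCm39; GRCm39 is a mouse build and its role is not given in the sources used here. Strand handling and the hairpin sequences are likewise not given in the sources used here.

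The authors deposited 3 tables, 1 per comparison, each holding only genes that passed their selection: every absolute log2 fold change is above 1, and every deposited p-value or q-value lies under a maximum. The largest deposited q-value is 0.0493 in the SQLE table and 0.0489 in the FDFT1 table, per the authors' deposited table. The lycorine table was selected on an unadjusted p under 0.05, and 142 of its genes have, by the authors' deposited table, an adjusted p of 0.05 or more. The SQLE and FDFT1 tables give whole-number counts per gene and library, per the file headers and values, and the lycorine table as deposited gives estimated counts, 84.3% of them whole, which were rounded before testing. The authors' log2 fold changes are treatment over control. A control column of each table has a description shared by a pair of samples, so it was assigned to its group and called the unnumbered control library. All library columns were used. The lycorine table had 1719 entries, and 10 that repeated a gene were left out. Each knockdown table holds 1 name that a spreadsheet turned into a date, which was not named. The SQLE table also lists genes of other types than protein-coding (95 of 449), and the lycorine table gives no gene type.

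The design had foreseen, before the data were examined, that a table of selected genes would be described by the authors' own calls. So the counts of changed genes are the authors' deposited calls at a q-value under 0.05. The libraries' scaling factors were recovered from the deposited log2 fold changes and counts, exactly for the knockdown tables and with a median residual of 0.000915 for the lycorine table. With these factors edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) was run on the listed genes, two-sided, group as the only term, within each table. Benjamini-Hochberg adjustment used the number of genes tested that the deposited p-values and q-values imply: 31112 in the SQLE table, which was also used for FDFT1 knockdown (30978 implied), and 14576 for lycorine hydrochloride. Because only selected genes enter, the dispersion (biological coefficient of variation 0.107, 0.151 and 0.0592) is estimated from genes with small spread for their change, and these adjusted p-values are too small by an unknown amount. Replicate pairs differed by more than counting noise in all groups, with a mean chi-square per gene between 3.97 and 34.1.

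The genes named were set by a rule fixed with the other choices named above: SQLE and FDFT1, the 12 largest rises and falls among genes past the threshold with groups that do not overlap and a mean above the lower quartile of the table, and up to 4 members of each gene list. Some genes that the rule names are not reported here. Genes outside the rule are said to be so where they occur. Lists, 43 in all, were fixed at the same time; each list's split between rises and falls was set against the rest of its table by Fisher's exact test, adjusted over the lists with a member past the threshold. This tests direction only and does not ask whether a list is over-represented.

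Overlaps used the deposited log2 fold changes of genes past the threshold in both tables. For the knockdowns, 2000 simulations of unchanged groups against the shared controls gave the relation that sharing alone produces, and a direct edgeR contrast of the knockdown groups gave the differences in size; for genes with opposite directions it is no separate test, since the tables were selected on fold change. Symbols were matched to GENCODE release 29 (GRCh38) to obtain gene positions, gene types and 3' UTRs. Every 7-base word was counted in 3' UTRs of at least 50 bases, covering 99.4%, 98.1% and 98.1% of the annotated protein-coding genes past the threshold, and its excess among fallen genes was set against 1000 permutations of the directions within 10 strata of 3' UTR length; the scan was repeated with permutations within 10 strata of 3' UTR GC content, each split at the median length.

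Tested on simulated counts with 200 changed genes, the edgeR step recovered 42%, 57% and 87% of genes changed by 1 log2 and 85%, 95% and 95% of those changed by 2 log2 on 449, 692 and 1709 genes, and called no unchanged gene. The adjustment there also used 31112 and 14576 genes, far more than were simulated, and the dispersion was that of the selected genes. So strict a cutoff leaves hardly any unchanged gene called in any case, so this does not measure the rate of false calls. Alternatives were TMM and DESeq2 (1.42.0) size factors from the listed genes, DESeq2's Wald test, a mean of at least 10 counts, a stricter adjusted p of 0.01, leaving out each library, and rank correlation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.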

Results

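The series profiled RNA from RBE, an established human cholangiocarcinoma (bile duct cancer) cell line, in 10 libraries that fall into 5 groups of 2. Control cells, cells with knockdown of SQLE and cells with knockdown of FDFT1 formed a first set, and cells given DMSO or 1 µM lycorine hydrochloride for 24 h formed a separate set. FDFT1 encodes squalene synthase, which joins farnesyl diphosphate into squalene, and SQLE encodes squalene epoxidase, which acts on squalene next. Lycorine is an alkaloid of plants of the amaryllis family. Each of 3 deposited tables lists only the genes that its authors called changed, so a gene missing from a table may have changed by less or may have been too low to test. Summed counts over the listed genes ran from 283286 to 515211 per library in the SQLE table, from 931188 to 1103958 in the FDFT1 table and from 1164184.6 to 2049641.7 in the lycorine table, and full library depths are unknown. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Genes are given by their symbols as listed; folds and log2 values come from a fit of edgeR's quasi-likelihood test with the authors' scaling, with a standard error (SE) and n = 2 per group throughout.

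The first comparison asked what changed when SQLE was knocked down. SQLE itself (chromosome 8, 124998497 to 125022283, plus strand, GRCh38) stood at 13851 and 14679 normalised counts in the control libraries and at 2989.6 and 3375 in the libraries labelled SQLE knockdown, a 4.48-fold fall (log2 -2.16 ± 0.11, adjusted p = 4.1e-17, edgeR). SLC17A1, a phosphate and urate transporter, rose 9.71-fold (log2 3.28 ± 0.27), and the cytokine gene CSF2 fell 8.71-fold (log2 -3.12 ± 0.32). AKR1C2, an aldo-keto reductase gene, rose 6.12-fold, and SAA1 and TNFRSF9 fell. By the authors' deposited table, 449 genes passed an adjusted p of 0.05, of which 204 rose and 245 fell.

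Among the largest rises after SLC17A1 were ADCY5, an adenylyl cyclase (5.52-fold), the calcium channel gene CACNA1D (5.21-fold), the transcription factor gene TFEC (3.92-fold), SEC14L5 (3.79-fold), the arrestin domain gene ARRDC4 (3.79-fold), the cadherin gene CDH17 (3.71-fold), ENPP5 (3.51-fold) and the calcium-binding protein gene SCGN (3.16-fold). ACSM2A (7.98-fold) also rose, but it shares reads with a close paralog, so its value is uncertain. The control libraries were far apart for some of these genes: CACNA1D stood at 60.4 ± 41.9 (SD, n = 2) normalised counts in the controls and 320.2 ± 44.1 in the knockdown. ARRDC4 was tighter, at 217 ± 13.9 against 821 ± 5.41. Besides CSF2 and SQLE, large falls were those of N4BP3 (4.94-fold), TNFRSF9, a receptor of the tumour necrosis factor family (4.51-fold), the activin-binding protein gene FST (4.22-fold), the mitochondrial dehydrogenase gene DHTKD1 (4.07-fold), GNG10 (4.02-fold), the mitochondrial import channel gene TOMM40 (3.95-fold), ROBO4 (3.88-fold), the integrin-binding gene FERMT2 (3.78-fold), SAA1 (3.76-fold) and UBD (3.62-fold). GNG10 overlaps a read-through locus and SAA1 has a near-identical paralog, so their values may include reads of a neighbour. DHTKD1 fell from 2878 ± 44.7 to 708 ± 51.1 normalised counts and TOMM40 from 5353 ± 480 to 1357 ± 55.8, both well beyond the spread between libraries. Falls that carry ATCATGT in the 3' UTR, a 7-base word taken up below, include DHTKD1, TOMM40, GNG10 and FERMT2. For these genes an effect of the hairpin itself stays possible.

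Members of 20 of the 43 gene lists passed the threshold in the SQLE knockdown, and no list was split between rises and falls differently from the rest of the table after adjustment. Sterol genes were almost missing from it: none of the 11 genes of the mevalonate pathway was listed, and SQLE was the only listed gene of the 13 that lead from squalene to cholesterol. Of the 16 genes in the list named for SREBP2 targets and sterol sensing, only MYLIP was listed, with a 2.67-fold rise (log2 1.42 ± 0.20). MYLIP encodes a ligase that marks the LDL receptor for degradation, and its rise is not read here as a rise of SREBP2 targets. All 4 NRF2 targets past the threshold rose (Fisher's exact p = 0.0419, adjusted 0.663): AKR1C2, AKR1C1 (2.35-fold), AKR1C3 (2.26-fold) and AKR1B10 (2.24-fold). These are paralogs that can share reads, so they are not 4 separate measurements. All 5 members past the threshold in the list of NF-kB targets and inflammatory cytokines fell (Fisher's exact p = 0.0663, adjusted 0.663), among them CSF2, SAA1, the interleukin gene IL11 (2.41-fold) and the chemokine gene CCL20 (2.52-fold). The desaturase genes SCD5 (2.38-fold) and FADS2 (2.32-fold) fell as well. Counts adjusted over the list alone were equal to those over all genes tested, at 32 memberships. The edgeR fit with the authors' factors called 202 genes up and 245 down. With factors computed from the listed genes, a median shift of 0.40 log2 with TMM, it called 204 up and 146 down, and with DESeq2's factors 204 up and 35 down, where IL11, SCD5, FADS2 and CDC25A lost their calls. CCL20 lost its call with TMM and with DESeq2 factors, with DESeq2's Wald test, and without the unnumbered control library, control replicate 2 or knockdown replicate 2, and the count of changed genes was 285 without the unnumbered control and 289 without knockdown replicate 1.

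The second comparison asked the same for FDFT1. FDFT1 (chromosome 8, 11795573 to 11839309, plus strand, GRCh38) stood at 11359.8 and 10794 normalised counts in the controls and at 596 and 679 in the libraries labelled FDFT1 knockdown, a 17.4-fold fall (log2 -4.12 ± 0.22, adjusted p = 1.5e-63, edgeR). Sterol synthesis genes fell together: all 19 listed members of 3 sterol lists other than FDFT1 were lower, by 2.16-fold to 6.61-fold, and SQLE fell 3.37-fold (log2 -1.75 ± 0.20). All 9 members past the threshold in the list of NF-kB targets and inflammatory cytokines rose, among them CXCL8 by 4.85-fold (log2 2.28 ± 0.23). STC2, a secreted glycoprotein gene, rose 9.85-fold (log2 3.30 ± 0.21), and HABP2, a secreted protease gene, fell 31.5-fold (log2 -4.98 ± 0.34). By the authors' deposited table, 692 genes passed an adjusted p of 0.05, of which 273 rose and 419 fell, and all of them are annotated as protein-coding there.

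Within the sterol genes, all 7 listed of 11 genes of the mevalonate pathway, FDFT1 included, fell, among them HMGCS1 (6.13-fold) and IDI1 (4.18-fold). All 8 listed of 13 genes from squalene to cholesterol fell, among them MSMO1 (4.47-fold), and so did all 5 listed of 16 SREBP2 targets and sterol sensors, with INSIG1 at 6.61-fold, the cholesterol uptake gene NPC1L1 at 6.55-fold and the sterol carrier gene STARD4 at 3.39-fold. Each of the 3 lists alone missed the threshold when its split was set against the other genes of the table (Fisher's exact test, adjusted p = 0.235, 0.169 and 0.439 over 27 lists). The stearoyl-CoA desaturase gene SCD fell 3.52-fold, from 37620 ± 3176 to 10684 ± 490.1 normalised counts (SD, n = 2).

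**Figure D1:**
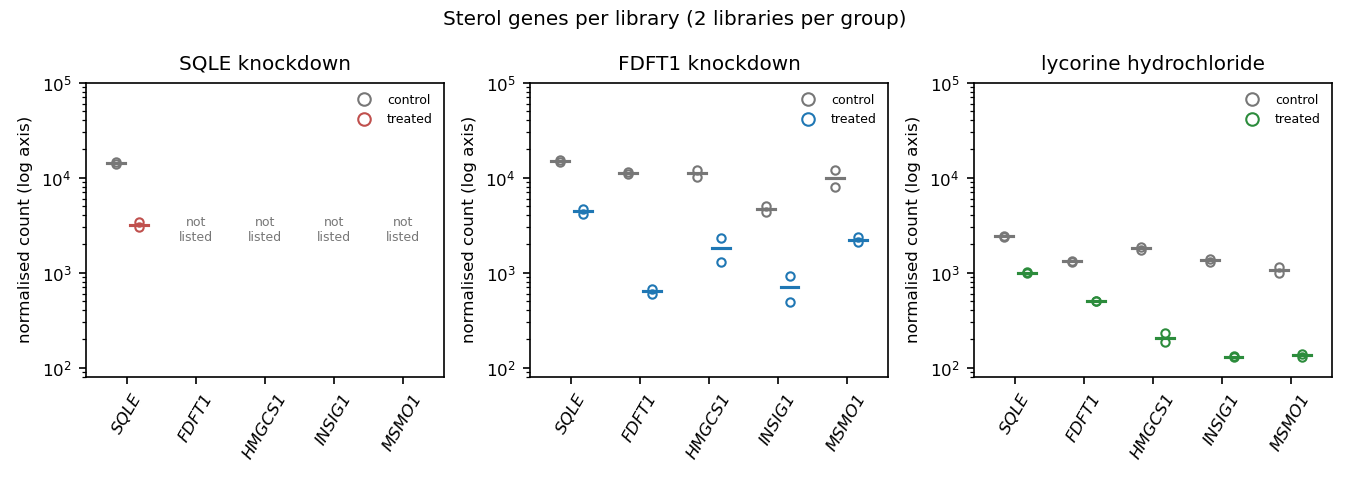
Normalised counts (log axis) of 5 sterol genes in each library, with open circles for the 2 libraries of a group and a bar at their mean; treated means knockdown or lycorine hydrochloride. In the SQLE table only SQLE is listed. In the other tables all 5 genes lie lower in both treated libraries than in both controls, from 11077 to 637 for FDFT1 in its own knockdown. With TMM factors from listed genes, SQLE and FDFT1 were not called with lycorine hydrochloride. Those genes were selected and mostly lower, so the factors move all lycorine values up, by a median of 1.21 log2, and do not test these falls.

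The NF-kB and cytokine list was the only list of the 27 tested to pass in the FDFT1 knockdown (9 of 9 up against 264 of the other 683 genes, Fisher's exact p = 0.000213, adjusted 0.00576). Its members include related chemokine genes, such as CXCL8 and CXCL5, that may move together or share reads. The 9 are thus not separate measurements, although the test treats them so. The result covers members of this list only: NFKBIZ, a gene outside the list and the naming rule, fell 3.60-fold (log2 -1.85 ± 0.21). CXCL5 was near the floor, at a mean of 1.02 normalised counts in the controls and 18.3 in the knockdown. CSF2 rose 4.86-fold and CCL20 4.65-fold, both genes that fell in the SQLE knockdown. All 5 listed ATF4 targets rose (adjusted p = 0.0841, Fisher's exact test), among them STC2, ADM2 (4.44-fold) and the transcription factor gene CEBPB (2.58-fold), and so did all 5 listed immediate early genes (adjusted p = 0.0841), among them FOSB (5.17-fold), NR4A1 (2.74-fold) and the phosphatase gene DUSP5 (2.55-fold). Of 5 genes of glycolysis and hypoxia 4 rose, among them the glucose transporter genes SLC2A3 (6.97-fold) and SLC2A1 (2.81-fold) and the carbonic anhydrase gene CA9 (3.36-fold); SLC2A3 can share reads with a close paralog. In the list of DNA replication and the G1/S transition, 3 of 3 rose, among them CDC25A (2.62-fold) and E2F1 (2.43-fold). Epithelial adhesion genes went both ways, with CDH1, which encodes E-cadherin, down 6.37-fold and EPCAM up 2.44-fold.

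Other large rises were LCP1, an actin-bundling protein gene (9.25-fold), the BMP antagonist gene NOG (6.91-fold), the transporter gene SLCO2B1 (6.33-fold), DACT1 (5.65-fold), the activin subunit gene INHBA (5.65-fold), JPH1 (5.46-fold) and the phosphatase gene PTPRR (5.04-fold). The knockdown libraries differed for some of them: INHBA stood at 218 ± 13.7 in the controls and 1228 ± 478 in the knockdown, and JPH1 at 62.1 against 339.8 ± 152. Other large falls were PRODH2 (15.6-fold), ANXA13 (14.6-fold), the gap junction gene GJB1 (14.5-fold), WDR72 (13.5-fold), the cadherin gene CDH16 (11.7-fold), OLFML3 (10.8-fold), the retinaldehyde dehydrogenase gene ALDH1A1 (10.6-fold) and the transporter genes SLC17A3 (9.88-fold), SLC5A9 (9.74-fold) and SLC23A1 (9.06-fold). Counts adjusted over the list alone were equal to those over all genes tested, at 89 memberships. The edgeR fit with the authors' factors gave the same split of 273 up and 419 down. With TMM factors from the listed genes, a median shift of 0.65 log2, it became 273 up and 136 down and 13 of the 19 sterol genes other than FDFT1 still fell, and with DESeq2's factors it became 273 up and 81 down, with 8 of the 19 still down. Without control replicate 2, 443 genes were called.

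The third comparison asked what changed after 24 h of 1 µM lycorine hydrochloride against DMSO. Genes in the list of ribosome biogenesis and MYC targets rose together, with all 14 listed of 30 higher. RRP12, a factor of ribosomal subunit maturation, rose 3.30-fold (log2 1.72 ± 0.10, adjusted p = 7.5e-62, edgeR). The stress-response phosphatase subunit gene PPP1R15A rose 5.08-fold (log2 2.34 ± 0.10) and NR1D1, a nuclear receptor gene of the circadian clock, 5.75-fold (log2 2.52 ± 0.11). The chemokine genes CXCL6 and CCL2 fell 37.6-fold (log2 -5.23 ± 0.19) and 13.9-fold, CDH1 fell 14.3-fold, and the tight junction gene CLDN2 fell 14.5-fold (log2 -3.86 ± 0.11). All 17 listed members of the 3 sterol lists were lower. With TMM factors from the listed genes, which move all values up by a median of 1.21 log2, 9 of them still fell and 5 changed sign. By the authors' deposited table, 1567 genes passed an adjusted p of 0.05, of which 481 rose and 1086 fell.

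Ribosome biogenesis and MYC targets were the only list of 35 whose split differed from the rest of the table after adjustment (14 of 14 up against 467 of 1553, Fisher's exact p = 5.8e-08, adjusted 2.0e-06). DKC1, a pseudouridine synthase gene, rose 2.99-fold, RRP9 2.86-fold and the methyltransferase gene NOP2 2.67-fold. Of 7 immediate early genes 6 rose (adjusted p = 0.0741, Fisher's exact test), with KLF4 at 3.58-fold, DUSP5 at 2.68-fold and JUN at 2.56-fold. The other large rises were the neurosecretory gene VGF (5.72-fold), OSGIN1 (5.05-fold), LINGO1 (4.29-fold), PLD6 (4.29-fold), the mucin gene MUC13 (4.15-fold), KBTBD8 (3.99-fold), the protease gene ADAMTS6 (3.96-fold), the zinc finger gene ZNF460 (3.95-fold), DHRS2 (3.95-fold) and ISM1 (3.92-fold). VGF went from 192 ± 28.0 to 1102 ± 31.6 normalised counts (SD, n = 2), while ISM1 and ZNF460 were below 20 in the controls.

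Of the sterol genes, INSIG1 fell 10.3-fold (log2 -3.36 ± 0.11), HMGCS1 8.69-fold, MSMO1 7.90-fold, FAXDC2 4.86-fold, the mevalonate kinase gene MVK 4.82-fold, STARD4 3.81-fold and IDI1 2.79-fold. FDFT1 fell 2.61-fold, from 1309 ± 19.3 to 501.2 ± 0.690, and SQLE 2.42-fold, from 2410 ± 58.6 to 994 ± 19.3. With TMM factors from the listed genes their log2 changes were -0.18 and -0.071, and neither was called. Because the listed genes were selected and mostly lower, these factors move all values up, by a median of 1.21 log2, so the loss of these calls follows from the selection. The 3 sterol lists each missed the threshold (adjusted p = 0.893, 0.755 and 0.893, Fisher's exact test). The cholesterol efflux transporter genes ABCA1 and ABCG1, both LXR targets, rose 2.85-fold and 3.50-fold, although ABCG1 was low, at 9.97 ± 3.07 against 34.5 ± 5.96.

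Of 13 NF-kB targets and cytokines past the threshold 11 fell and 2 rose, with CXCL1 down 7.69-fold (adjusted p = 0.914, Fisher's exact test). With TMM factors 6 of the 11 falls were still called and 1 of the 13 changed sign. The 13 members past the threshold in the list of ATF4 targets were split, 9 down and 4 up, with ATF4 itself among the rises. The serine synthesis gene PHGDH fell 6.77-fold and the amino acid transporter gene SLC7A5 3.98-fold, beside the rise of PPP1R15A. With TMM factors 5 of the 9 falls were still called and 1 changed sign. All 5 listed p53 targets were lower, with TP53INP1 down 4.66-fold and the pro-apoptotic gene BBC3 down 3.19-fold. With TMM factors 4 of them still fell and 1 changed sign. Of 6 interferon response genes 5 fell, with IFIT1 down 9.76-fold and OAS1 down 4.55-fold. With TMM factors 3 of the 5 falls were still called and 2 genes changed sign. All 9 listed mitochondrially encoded mRNAs were lower (adjusted p = 0.752, Fisher's exact test), with MT-ND6 at 3.22-fold and MT-ATP8 at 2.98-fold. With TMM factors 2 of the 9 falls were still called and 6 changed sign, and both named genes overlap or face neighbours. In the cell-cycle list of G1 cyclins and inhibitors, CDK6 rose 2.30-fold and the inhibitor gene CDKN2C fell 4.08-fold. The other large falls were the semaphorin receptor gene PLXNA4 (37.9-fold, from 85.6 to 2.14 normalised counts), the collagen gene COL9A2 (16.0-fold), SORBS2 (12.3-fold), the bradykinin receptor gene BDKRB2 (11.9-fold), PIK3IP1 (11.8-fold), the glucose transporter gene SLC2A12 (11.4-fold) and SLCO2B1 (log2 -3.46 ± 0.34). Adjusted over the list alone, 147 memberships passed, against 151 over all genes tested. The edgeR fit with the authors' factors called 503 genes up and 1206 down over all 1709 listed genes. With TMM factors from the listed genes, a median shift of 1.21 log2 that can only add to rises, it called 503 up and 275 down and 304 genes changed sign, and with DESeq2's factors 503 up and 256 down with 298 changes of sign.

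**Figure D2:**
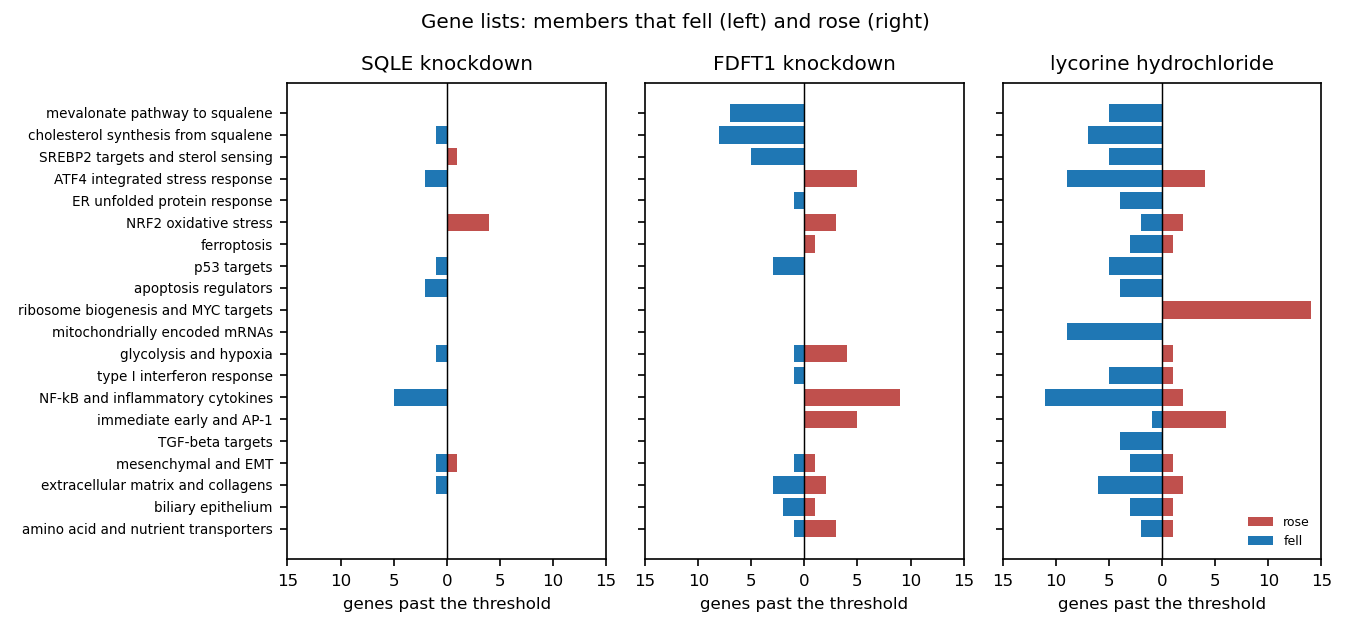
Members of each gene list past the threshold (bars, in genes, each starting at 0), those that fell to the left and those that rose to the right, for lists with at least 4 such members in 1 comparison. The list of ribosome biogenesis and MYC targets shows 14 rises with lycorine hydrochloride, and that of NF-kB targets and inflammatory cytokines 9 rises with FDFT1 knockdown. With TMM factors from listed genes, 6 of the 9 falls of mitochondrial mRNAs and 5 of the 17 of sterol genes with lycorine hydrochloride changed sign. These factors move all lycorine values up, by a median of 1.21 log2, so smaller falls change sign by construction.

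SQLE and FDFT1 act in sequence, and the knockdowns were compared gene by gene. They shared 71 changed genes, of which 53 moved in opposite directions and 18 in the same direction (7 up in both and 11 down in both; Fisher's exact p = 3.9e-05). Genes such as SLC17A1, SLC17A3, SLC5A9, SLC23A1, GJB1, ANXA13 and ALDH1A1 were higher with SQLE knockdown and lower with FDFT1 knockdown, while CSF2, CCL20, SAA1, LCP1 and CDC25A were lower with the former and higher with the latter. Of the 18 genes with the same direction, 8 differed in size in a direct edgeR contrast of the knockdowns. Across these 71 genes, which are not independent replicates, Pearson's r was -0.50 and Spearman's rho -0.47. The control libraries were the same in both tables (identical counts in 71 of 71 genes), which alone gives a positive relation. Unchanged groups simulated against them gave a median r of 0.50 and a covariance of 0.0346, against an observed covariance of -1.62. Only the signs can be compared, since the simulated changes were not selected for size and the observed ones were. If 14576 genes were tested in both, independent lists would share 2.77 genes up in both, 5.92 down in both and 4.25 and 3.86 in opposite directions, against 7, 11, 27 and 26 found. These expected numbers use only the 354 protein-coding genes of the SQLE table, as the FDFT1 table lists no others.

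The lycorine response was set beside each knockdown to see whether the same genes moved. With FDFT1 knockdown it shared 213 genes, of which 153 were lower in both, 28 were higher in both and 32 were higher with the knockdown and lower with the compound (Fisher's exact p = 1.3e-18); r across genes was 0.53 and rho 0.46. Sterol genes such as INSIG1, HMGCS1 and MSMO1 and the cadherin gene CDH1 were among those lower in both. Independent lists would share 31.2 genes lower in both, 9.01 higher in both, 20.3 higher with the knockdown and lower with the compound, and 13.8 of the reverse kind, of which none was found. With SQLE knockdown it shared 85 genes, 33 in the same direction and 52 in opposite directions (Fisher's exact p = 0.00357), with r = -0.47 and rho = -0.47. Of these, 3 were higher in both, 30 lower in both, 36 higher with the knockdown and lower with the compound, and 16 the reverse, against 6.73, 18.3, 15.2 and 8.08 for independent lists. These expected numbers use all 449 genes of the SQLE table, not only its protein-coding genes as for the knockdowns, and fewer genes would give smaller numbers. The genes of both overlaps are not independent replicates, so the p-values of these Fisher's exact tests do not measure the spread between cultures. By their titles, the control libraries of the lycorine set were separate. None of 321 pairs of a knockdown and a lycorine entry for the same gene had equal counts in the first control columns, with genes in all 3 tables counted more than once. Whole-number and estimated counts could differ for the same library as well, so these counts do not settle it.

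**Figure D3:**
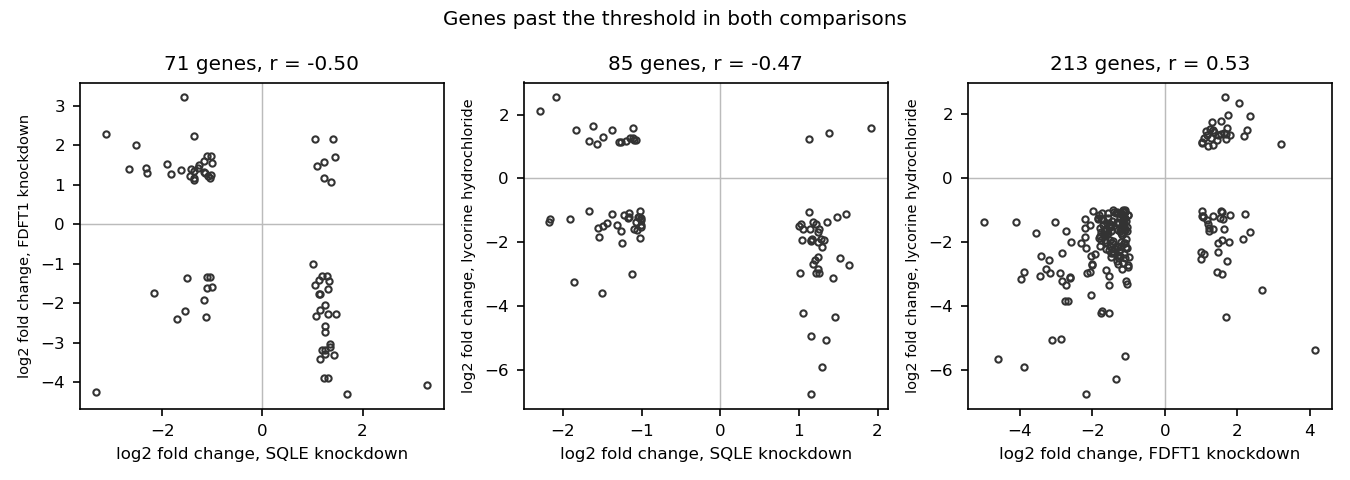
Log2 fold changes from the authors' deposited tables for genes past the threshold in both comparisons of a pair, 1 point per gene, for 71, 85 and 213 genes. The empty bands around 0 come from the tables' own minimum fold change; r is -0.50, -0.47 and 0.53, and the lycorine values move up together by 1.21 log2 with TMM factors from listed genes.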

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

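The tests of shared controls, of exchanged labels and of genes with a 3' UTR word were chosen after the opposite fold changes had been seen.

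In the direct edgeR contrast of the knockdowns, 53 genes with opposite directions differed. Both tables were selected for an absolute log2 fold change above 1, so a difference above 2 follows from the selection for these genes, and the contrast is no separate test of them. As SQLE knockdown minus FDFT1 knockdown, the log2 difference was 7.28 for SLC17A1, 5.87 for SCGN, 5.16 for GJB1, 5.09 for ANXA13, 4.73 for SLC17A3, 4.55 for ALDH1A1, 4.53 for SLC5A9 and 4.38 for SLC23A1. The values of SLC17A1 (SE 0.43) and SCGN (SE 0.57) rest on low counts, with control means of 24.2 and 27.7 normalised counts, so their sizes are uncertain. The log2 difference was -5.41 for CSF2, -4.77 for LCP1, -3.74 for N4BP3, -3.56 for CCL20, -3.45 for SAA1 and -2.82 for CDC25A. SQLE was lower in both knockdowns and differed by -0.41.

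The shared genes of the knockdowns moved mostly in opposite directions, although the enzymes act in sequence. Shared control libraries push the relation the other way: the simulated covariance was positive, with a range of 0.0175 to 0.0561, and the observed one was negative, at -1.62. The sizes cannot be compared, since the simulated changes were not selected for size. An exchange of labels between the knockdowns is argued against by FDFT1, at log2 -4.12 in the libraries labelled FDFT1 knockdown. Genes with a 3' UTR word enriched among the falls of either table do not carry the pattern, since r without them was -0.64 (bootstrap 95% interval -0.80 to -0.44). The bootstrap drew genes, which are not independent replicates, so this interval may be too narrow. Both tables list only strong changes, so the relation among weaker ones is unknown. A difference between the biology of SQLE loss and FDFT1 loss, and further off-target effects of either hairpin, stay open and were not tested.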

How the results depend on the processing

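The SQLE counts for protein-coding genes alone and without word-carrying genes, the lycorine count at an unadjusted p, the correlations without word-carrying genes and those of the lycorine overlaps without a control were chosen after the data were seen; the other alternatives were planned. No gene changed sign under any alternative in a comparison for which its value is given; of all 117 genes that the naming rule gives for lycorine hydrochloride, 15 changed sign with TMM and with DESeq2 factors, none past the threshold, and none did in the knockdowns. The counts of changed genes fell most where scaling factors came from the listed genes alone, which are selected and mostly lower: to 239 for SQLE knockdown (DESeq2 factors), to 409 (TMM) and 354 (DESeq2 factors) for FDFT1 knockdown, and to 778 and 759 for lycorine hydrochloride, against 447, 692 and 1709 in the same fit with the authors' factors and 449, 692 and 1567 by the authors' deposited calls. Without word-carrying genes the SQLE knockdown kept 357 genes, 191 up and 166 down against 204 and 245, as the word was picked for its excess among falls. DESeq2's Wald test called 246 genes for SQLE knockdown; the cause was not tested. Leaving out 1 library in turn, so that the lone library was assumed to vary like the others, gave 285 to 320 genes for SQLE knockdown (285 without the unnumbered control, 289 without knockdown replicate 1), 443 to 660 for FDFT1 knockdown (443 without control replicate 2) and 1613 to 1663 for lycorine hydrochloride. With lycorine hydrochloride, SQLE was at log2 -0.071 with TMM and -0.076 with DESeq2 factors, and FDFT1 at -0.18 with both, neither called; the median shift of 1.21 log2 shows the cause. The relation of the knockdowns was -0.56 with the unnumbered control for SQLE and control replicate 2 for FDFT1, -0.47 the other way round, -0.50 without either control, and -0.64 without word-carrying genes (single knockdown libraries gave -0.42 to -0.53); that of SQLE knockdown with lycorine hydrochloride was -0.51 without them, and rho between FDFT1 knockdown and lycorine hydrochloride was 0.46 against r = 0.53; the cause of these shifts was not tested. A minimum of 1 on the absolute log2 fold change removed nothing from the authors' deposited calls, as the tables were selected on it. In the edgeR fit with the authors' factors it left 443 of 447 genes for SQLE knockdown, all 692 for FDFT1 knockdown and 1706 of 1709 for lycorine hydrochloride. With TMM factors from the listed genes it left 268 of 350, 381 of 409 and 645 of 778. No paired analysis was possible from the column labels alone, because 1 control column of each table carries no replicate number. Elimination within its group would make it replicate 1, but a fit that pairs libraries on that basis was not run. The labels do not say that libraries with equal numbers form a pair. Set tests with an estimated correlation (camera, fry) were not run, since they need unselected genes. Other pseudocounts do not apply to the count tests. The correlations with controls split or left out and with single libraries used a pseudocount of 0.5, and no other was tried. On that basis r of the knockdowns with all libraries was -0.51. No filter on low counts was applied to begin with. The tables show neither full depth nor genes with smaller changes, so no statement covers genes that are not listed.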

Other observations

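The tests of 3' UTR words, transcript types, gene families and the combined sterol lists were chosen after the results had been seen, 4 of them on gene groups of the lycorine table, and the genes named here fall outside the naming rule unless given above.

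With lycorine hydrochloride, zinc finger genes (symbols with ZNF, ZSCAN or ZKSCAN) went against the table, with 28 up and 8 down (77.8% up against 29.6% of the other genes, Fisher's exact p = 5.2e-09), and 2 of the 36 changed sign with TMM factors from the listed genes. All 5 listed non-coding host genes of small nucleolar RNAs rose (Fisher's exact p = 0.00269), among them SNHG1 (3.16-fold, log2 1.66 ± 0.10), ZFAS1 (2.66-fold) and GAS5 (2.06-fold); the 20 hosts searched were listed from general knowledge. Of 13 read-through loci 9 rose (Fisher's exact p = 0.00463), several from no counts in the controls, and their reads cannot be separated from those of the genes they join. Many of these host transcripts are known targets of nonsense-mediated decay, which needs translation, so a loss of that decay was a candidate explanation. Protein-coding genes with an annotated transcript of this kind rose in 28.7% of cases against 31.1% of the others (Fisher's exact p = 0.371). With genes split by control level into 3 equal parts, from low to high, the shares were 18.8% against 24.3%, 22.9% against 32.3% and 42.2% against 37.4% (Fisher's exact p = 0.202, 0.0353 and 0.296). They went different ways, which does not show a loss of decay and, since most of their transcripts are of other types, leaves it open.

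The fall of many genes in the SQLE knockdown may come from the hairpin itself. The word ATCATGT stood in the 3' UTR of 79 of 200 fallen genes (39.5%) and 13 of 146 risen ones (8.90%), the strongest of all 7-base words, with a permutation p of 0.001, the smallest that 1000 permutations can give; it showed no such excess in the FDFT1 table (10.8% against 10.6%, Fisher's exact p = 1) or the lycorine table (10.2% against 12.5%, p = 0.226). It occurs in the SQLE mRNA, in the coding part of exon 2 (chromosome 8, 125003399 to 125003405, GRCh38), as do 15.7% of all such words, and 16 of the 20 falls with the smallest p other than SQLE carry it, among them PTPN11 (3.60-fold), DHTKD1, FERMT2 and MYOF (2.48-fold). Fallen genes had 3' UTRs richer in G and C (median 46.8% against 39.2%), but base composition is argued against, since the permutation p stayed at 0.001 with directions permuted within strata of GC content and length. The scan could come out otherwise: the lycorine table, with no hairpin, also gave a best word at a permutation p of 0.001 (CAGCCCC), which went to 0.197 within those strata. Longer 3' UTRs do not explain it either, as the median was longer in risen genes (1612 against 1235 bases). Silencing through this exact word alone is argued against for the 121 fallen genes without it in the 3' UTR, the only part searched (SQLE, with the word in its coding part, counts among them). The second word of the scan, TCATGTA, overlaps ATCATGT in all but its last base. It stood in 54 of 200 fallen and 16 of 146 risen genes (permutation p = 0.03). How many of the 121 carry it or a shorter match was not counted. The values are consistent with seed-matched silencing of part of the fallen genes, a hypothesis that the hairpin sequence would test; an endogenous small RNA with the same seed and effects of SQLE loss were not tested.

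SREBP2 targets are known to rise when cells lack sterols, so the fall of all 19 listed sterol genes other than FDFT1 with FDFT1 knockdown goes against a simple loss of sterol (combined Fisher's exact p = 6.7e-05 against the rest of the table). The word most enriched among falls of that table, GTATCTC (permutation p = 0.035, and 0.049 within strata of GC content and length), is argued against as the cause: 1 of the 19 sterol genes other than FDFT1 carries it, against 55 of 378 other fallen genes (Fisher's exact p = 0.495), so a word that most of them lack in the 3' UTR leaves their fall unexplained. For the other genes of that table it stays open. GTATCTC lies in the FDFT1 mRNA, as do 23.7% of all 7-base words. It had no such excess among falls in the SQLE table (3.50% against 8.22%, p = 0.0919) or the lycorine table (6.98% against 5.41%, p = 0.292, Fisher's exact tests). In this GTATCTC is like ATCATGT, but at a permutation p close to the threshold. The authors' scaling stays open: 13 of the 19 still fell past the threshold with TMM factors and 8 of the 19 with DESeq2 factors from the listed genes, and none changed sign. Those genes were selected and mostly lower, so such factors move all values up, by a median of 0.65 log2 with TMM. Falls near the minimum then lose their call whatever the true scaling is, so these counts cannot decide the question. A response to metabolites upstream of squalene synthase, other off-target effects and differences in culture between the groups stay open and were not tested. The fall of 17 sterol genes with lycorine hydrochloride (p = 0.00266, Fisher's exact test) is similar in direction, and whether it shares a cause was not tested. With TMM factors from the listed genes 5 of the 17 changed sign. These factors move all lycorine values up, by a median of 1.21 log2, so smaller falls change sign by construction.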
